A study of Rattus norvegicus with 10 samples.

How the data were processed

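Liver samples of 10 Harlan Sprague Dawley rats, 5 controls and 5 fed HMB at 10000 ppm for 13 weeks, were each hybridised to 1 Affymetrix rat genome expression array with a biotin label. The deposited table holds log2 signal values for 31099 probe sets, made with RMA (background adjustment, normalization between arrays and summary to 1 value per probe set) per the submitters' processing notes, which give no version. The values are used as the authors deposited them, in log2 units. No detection calls, raw intensity files, sex, cage, litter, slide or date were available. Rats were housed 5 per cage, so each group of 5 may have been 1 cage. The tests treated the animals as independent. Replicate numbers follow the order of deposition. No paired analysis was possible because the numbers pair no animals. No 2 arrays held identical values in any of the 45 pairs. The 57 Affymetrix control probe sets were left out of the tests and used for array measures, 24 for the poly-A transcripts added to the RNA and 18 for the hybridisation controls.

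Groups were taken from the titles and chemical labels. HMB replicate 1 has a dose label of 0 ppm against an HMB title and chemical label, and an alternative counted it as a control. Probe sets were named from the platform annotation. Of the 31042 tested, 20826 had 1 gene symbol, 436 had several and stayed unnamed, and 9780 had none. Symbols were updated through gene identifiers to the rat RefSeq table of assembly GRCr8, which matched for 20764 probe sets. That table served for names only, and no coordinates are given. Each of 14217 genes was represented by the probe set with the highest mean over all 10 arrays, a choice needed for the 4525 genes with more than 1.

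Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with the default prior, HMB minus control, and Benjamini-Hochberg adjustment over all probe sets or all genes tested. The threshold was an adjusted p of 0.05, and counts at 1.5-fold required this and an estimated fold of 1.5 in either direction. The fit had 8 residual degrees of freedom and a prior of 4.93 for probe sets. No filter on low signals was applied. Tested on simulated data of 14217 genes with the spread of these arrays, the step recovered 54% of genes changed by 0.5 and 96% of genes changed by 1 on the log2 scale, with 5 false calls. With 31042 probe sets it recovered 43% and 96%, with 3 false calls. Simulated values were drawn independently for each gene or probe set, without differences shared across an array. These rates therefore need not hold for the measured arrays.

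Gene lists for pathways, liver cell types, other tissues and tissue handling, 39 in all, were fixed before the data were examined, and the 38 with at least 5 measured members were tested. Camera used a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over lists. Each list's mean log2 value per animal was compared by an exact two-sided permutation test over all 252 assignments of 10 animals into 5 and 5. List members were matched by symbol or through synonyms in the RefSeq table. After the data were seen, the synonym matching was narrowed, so that a name that is the current symbol of another gene is not taken as a synonym, because it had put wrong genes into 5 lists.

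The named genes followed a rule fixed before the data were examined. These are the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, passing over unnamed transcripts, then up to 4 members of each list with the smallest p, and a fixed set with Cyp1a1, Cyp1a2, Cyp2b1, Cyp2b2, Cyp3a23-3a1, Cyp4a1, Cyp7a1, Nqo1, Cdkn1a and Mki67. Exceptions are marked as chosen after their values were seen.

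Other settings, listed before the data were examined, were cyclic loess normalization, arrays set to the same median, filters leaving out the lowest 25% or 50% of mean levels, a trended robust prior, array weights, an adjusted p of 0.01, limma treat against 1.2-fold, the first principal component of the residuals as a covariate, another choice of probe set per gene, and each animal left out in turn. Added after the data were seen were quantile normalization, the poly-A signal as a covariate, and fits without HMB 3 to 5 or without HMB 1 and 2. Chance was assessed on 100 of the 126 splits of the animals into 5 and 5, drawn with seed 1 and including the real one. Random lists matched on expression level numbered 10000 per list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.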

Results

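Liver RNA from 10 Harlan Sprague Dawley rats was measured on rat genome expression arrays, with 1 array per animal. The 5 rats of the HMB group received HMB (2-hydroxy-4-methoxybenzophenone, also called oxybenzone, an ultraviolet filter used in sunscreens) at 10000 ppm in the feed for 13 weeks, and 5 control rats received 0 ppm. The title and the chemical label of HMB replicate 1 placed it in the HMB group, while its dose label read 0 ppm. It was kept in the HMB group, and the counts with it in the control group are given with those for left-out animals. No sex, cage, litter or array date was given for any animal. Rats were housed 5 per cage, and if each group was 1 cage, cage and HMB cannot be told apart. The values covered 31042 probe sets, of which 20826 named exactly 1 gene, and these represented 14217 genes. Correlations between pairs of arrays, across probe sets that are not independent replicates, ran from 0.987 to 0.995. The number of arrays, 5 per group, limited the precision of every comparison.

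The comparison asked which liver genes differed after 13 weeks between rats fed 10000 ppm HMB and rats fed none. In the HMB rats, 4 of 35 measured transcripts in a list of PPAR-alpha targets, most of fatty acid oxidation, rose and 31 did not pass. Among the 4 were Eci1, an enoyl-CoA isomerase of mitochondrial beta-oxidation, and Cyp4a1, a fatty acid hydroxylase. Cyp1a1, the monooxygenase induced through the aryl hydrocarbon receptor (AhR), rose from a low level. A larger log2 rise, of 1.40, was called in a probe set assigned to 2 targets of the receptors CAR and PXR at once. That probe set entered no gene test and was singled out after its values were seen. Transcripts of Ccnd1, a cyclin of cell cycle entry, and of Rora, a nuclear receptor of the circadian clock, fell. Among 14217 genes, 244 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 108 of them higher and 136 lower in HMB. With each array set to the same median, the number of genes changed by HMB was 320, 86 higher and 234 lower, with 27 higher and 229 lower probe sets changed by HMB at least 1.5-fold. At probe set level 528 of 31042 changed, 219 upward and 309 downward, and 179 of these changed at least 1.5-fold, 35 upward and 144 downward. At least 1.5-fold changes were seen in 69 genes, 18 of them higher and 51 lower. The calls lay close to the threshold, with a smallest adjusted p of 0.0294 over genes, and 3538 genes had an unadjusted p under 0.05 where chance would give 711. In 220 of the 244 genes the 5 HMB values and the 5 control values did not overlap. Over all genes 870, or 6.12%, showed no overlap, where chance gives 0.794%.

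The 10 named genes with the largest rises were chosen among called genes with all 5 HMB animals above all 5 controls. Larger log2 rises, of 1.40 and 4.46, were called in probe sets that do not name exactly 1 gene. Those probe sets entered no gene test and were singled out after their values were seen. Wfdc21, a protein with a WAP domain, rose by 0.93 ± 0.18 on the log2 scale (SE, n = 5 per group, limma adjusted p = 0.0319). Cyp1a1 rose by 0.92 ± 0.19 (adjusted p = 0.0414), from a mean log2 signal of 3.45 ± 0.38 (SD, n = 5) in controls to 4.37 ± 0.33 in HMB. Eci1 rose by 0.70 ± 0.10 (adjusted p = 0.0294) from 10.81 ± 0.20 to 11.51 ± 0.10, and Cyp4a1 rose by 0.69 ± 0.14 (adjusted p = 0.0414) from 10.29 ± 0.24 to 10.98 ± 0.27. The other 6 had log2 rises of 0.72 for Hap1, 0.72 for Dusp13b, 0.69 for Begain, 0.67 for Mmd2, 0.65 for Tff3, a secreted trefoil peptide, and 0.64 for Grin2c, a glutamate receptor subunit. Hap1, Dusp13b, Begain, Mmd2, Tff3 and Grin2c had control means between 3.56 and 4.50. Among 14 of the 20 genes with the largest rises and falls the call held after cyclic loess normalization (adjusted p from 0.0361 to 0.0775 over the 20). Cyp1a1 then had a log2 difference of 0.82 (adjusted p = 0.0775) and Cyp4a1 of 0.74 (adjusted p = 0.0523). Over the 18 settings in which named genes were compared, the limma adjusted p of Cyp1a1 ran from 0.0184 to 0.279. That of Cyp4a1 ran from 0.0362 to 0.334. Arrays at the same median, the filters on mean level, the residual component and the other choices of probe set were not among these settings.

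The 10 named genes with the largest falls were likewise chosen among called genes with all 5 HMB animals below all 5 controls. Vxn fell by 1.41 ± 0.23 on the log2 scale (SE, n = 5 per group, limma adjusted p = 0.0294), and Ppp2r2b, a regulatory subunit of a protein phosphatase, fell by 1.28 ± 0.27 (adjusted p = 0.0414). Prcp, a carboxypeptidase, fell by 1.26 ± 0.21 (adjusted p = 0.0296), with 4 HMB animals between 5.68 and 5.82 and HMB 5 at 6.87. Ccnd1 fell by 1.12 ± 0.20 (adjusted p = 0.0296) from 8.90 ± 0.46 (SD, n = 5) to 7.78 ± 0.27, and both of its other probe sets fell as well, by 1.16 and by 1.04. Smaller falls were measured for Car1, a carbonic anhydrase, at -1.06, Ajuba at 0.501-fold (7.69 to 6.69), Rora at -0.94, Slc34a2, a sodium-phosphate cotransporter, at -0.91, Wwc2 at -0.90 and Fam89a at -0.84. Dimmer second probe sets of Vxn, Ajuba and Rora had log2 differences of 0.16, 0.01 and 0.22, with none of the 3 called (adjusted p from 0.203 to 0.973).

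**Figure D1:**
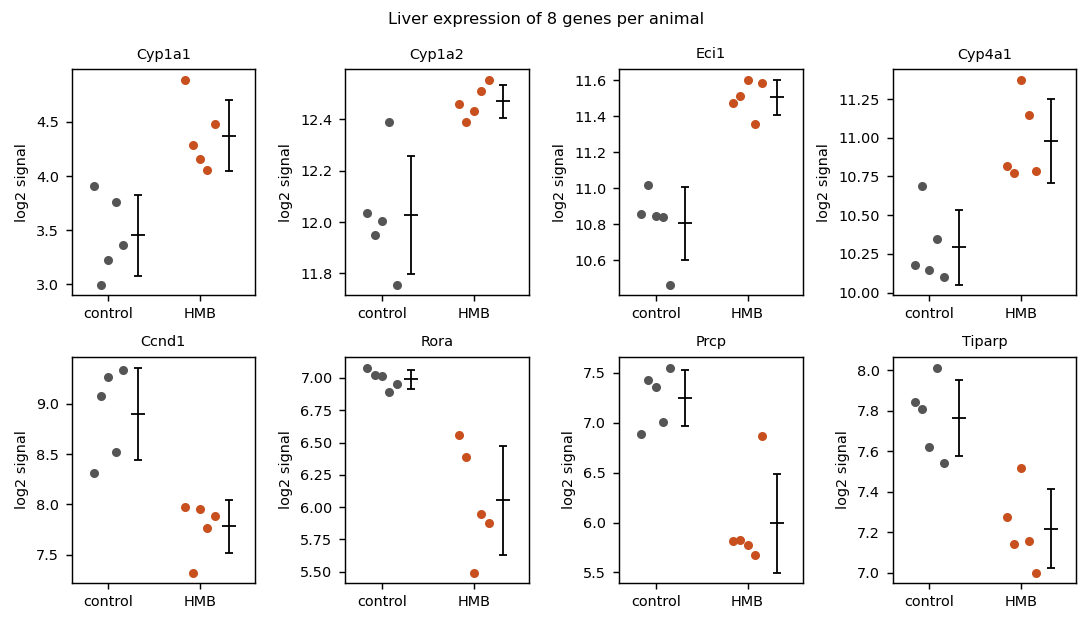
Log2 signal (y axis) of 8 genes in each of the 5 control and 5 HMB rats; points are animals, and the horizontal and vertical bars are the group mean and SD. In all 8 genes the HMB animals lie on 1 side of all controls, which was part of the rule that chose Cyp1a1, Eci1, Cyp4a1, Ccnd1, Rora and Prcp. Cyp1a2, with a limma adjusted p of 0.0545, is the only one of the 8 not called.

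These calls depended on single arrays. The number of genes changed by HMB was 1014 without control 1 and 353 without HMB 1, but 0 without control 2, control 3, control 5 or HMB 2. It was 15 without control 4, 157 without HMB 3, and 1 without HMB 4 or HMB 5. Where limma called 0 genes, between 2772 and 3434 genes had an unadjusted p under 0.05. With HMB 1 counted as a control by its dose label, 30 genes changed, 18 of them among the 244, and the Cyp1a1 log2 fold change was 0.55 (adjusted p = 0.254). The same setting gave 532 probe sets changed by HMB, 184 of them among the 528, 206 probe sets changed by HMB at least 1.5-fold, and 8 gene lists shifted by HMB.

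Array measures differed between the groups. The SD of all log2 values on an array was 2.47 ± 0.0236 (SD, n = 5) in controls and 2.40 ± 0.0261 in HMB, with all HMB arrays below all controls (exact two-sided permutation p = 0.00794, the smallest that 252 splits allow, and adjusted p = 0.0317 over 8 array measures). The signal of the poly-A control transcripts, which are added to the RNA before labelling, minus that of the hybridisation controls was -2.04 ± 0.106 in controls and -1.73 ± 0.225 in HMB (exact two-sided permutation p = 0.0238, adjusted p = 0.0635). HMB 3, HMB 4 and HMB 5, at -1.54, -1.78 and -1.47, lay above all 5 controls, while HMB 1 at -1.92 and HMB 2 at -1.96 did not. The 3' minus 5' signal of GAPDH split the same animals. It was 1.97, 2.09 and 1.90 in HMB 3 to 5, above all controls (up to 1.77). In HMB 1 and 2 it was 1.31 and 1.378, below all controls (1.383 or higher). For beta-actin, HMB 1 and 2 also lay below all controls, but of HMB 3 to 5 only HMB 4 lay above them. With HMB 3 to 5 left out, limma called 0 genes changed by HMB, with 1612 at an unadjusted p under 0.05. With HMB 1 and 2 left out it called 704, of which 193 were among the 244. With the poly-A signal as a covariate 0 genes passed, with 1914 at an unadjusted p under 0.05. These 3 fits were chosen after the data were seen.

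**Figure D2:**
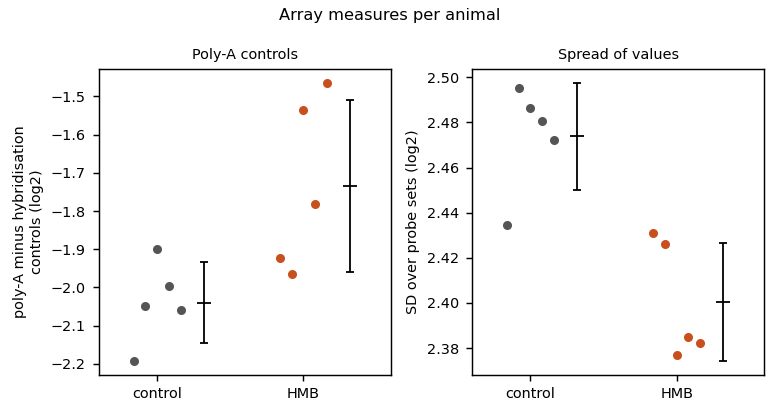
Array measures for each of the 10 animals, with group mean and SD. Left, mean log2 signal of the poly-A controls minus that of the hybridisation controls, where 3 of 5 HMB arrays lie above all controls; right, SD of the log2 values over probe sets, where all 5 HMB arrays lie below all controls.

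Rises and falls were unevenly spread over expression levels. Of the 32 genes called among the 3555 with the lowest mean signal, 31 rose. In the next 3554 genes, 62 of 102 calls were rises. Among the 3554 genes above those, 8 of 73 calls were rises, and among the 3554 brightest, 7 of 37. The median log2 difference of all genes in these 4 groups was 0.11, 0.03, -0.12 and -0.07. After cyclic loess the shares of rises were 66.7%, 51.1%, 52.6% and 69.2%, and 82 genes changed, 45 upward and 37 downward. Of the 244 genes, 75 were called under both scalings, 38 higher and 37 lower in both. The median of all genes was -0.02 before and 0.01 after that normalization.

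**Figure D3:**
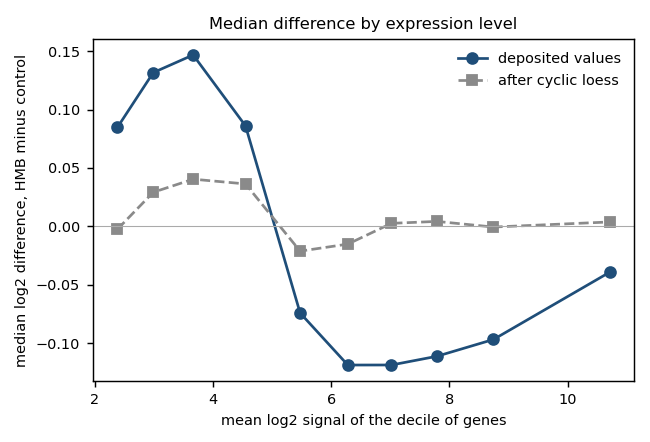
Median log2 difference, HMB minus control (y axis), for 10 groups of genes ordered by mean log2 signal (x axis). Circles are the deposited values and squares the values after cyclic loess; the deposited values lie above 0 for the dim genes and below 0 for the bright genes.

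Among the lists fixed in advance, targets of the AhR lay higher in the HMB rats. Of 8 measured members, Cyp1a1 rose and Tiparp, itself an AhR target that represses the receptor, fell by 0.55 ± 0.11 (SE, n = 5 per group, limma adjusted p = 0.0414), and 6 did not pass. Adjusted over the list alone, 6 members rose and 1 fell. Fewer than 5 of the 8 remained when the lowest 25% of mean levels was left out. The members left out there were dim, and dim genes lay higher in HMB. Random lists matched on level had a median log2 difference of 0.05. Cyp1a2, the constitutive liver monooxygenase of the family, differed by 0.44 ± 0.10 (adjusted p = 0.0545) from a bright 12.03, Nqo1 by 0.65 ± 0.22 (adjusted p = 0.114) and Cyp1b1 by 0.24 ± 0.08 (adjusted p = 0.101). The list's median log2 difference was 0.27, and camera called it higher than other genes (adjusted p = 0.0117), a call lost with an estimated correlation (adjusted p = 0.577 with an estimated correlation, the highest of its alternatives, which went down to 0.00593). The mean of the list was higher in 5 of 5 HMB animals than in any control, 0.29 apart (exact two-sided permutation p = 0.00794, the smallest that 252 assignments allow, and adjusted p = 0.201 over 38 lists). After cyclic loess 0 members were called (Tiparp at -0.43, adjusted p = 0.112) and the median was 0.16, with camera still calling the list (adjusted p = 0.041). Quantile normalization, chosen after the data were seen, left a median of 0.16 and ended the call (adjusted p = 0.0742).

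Fatty acid oxidation genes under PPAR-alpha, the receptor of peroxisome proliferators, were the list with the smallest p by camera at the preset correlation. Of 35 measured members, 4 rose, none fell and 31 did not pass. The 4 were Eci1, Cyp4a1, Pex11a, a protein of peroxisome division, by 0.61 ± 0.11 (SE, n = 5 per group, limma adjusted p = 0.0319), and Decr1, a mitochondrial dienoyl-CoA reductase, by 0.37 ± 0.08 (adjusted p = 0.0414). Adjusted over the list alone, 14 rose and 1 fell, the latter Fgf21, a secreted fasting hormone with a log2 difference of -0.87 (adjusted p = 0.084 over all genes). The list's median was 0.18, with 25 members above 0 and 10 below (camera adjusted p = 0.000143, and adjusted p = 0.685 with an estimated correlation, the highest of its alternatives, which went down to 7.99e-08). In 4 of 5 HMB animals the mean of the list exceeded that of every control, and HMB 4 lay below control 2 (difference 0.18, exact two-sided permutation p = 0.0159, adjusted p = 0.201). By fry, which asks whether a list's genes move on balance in 1 direction, the AhR list (adjusted p = 0.0290) and the PPAR-alpha list (adjusted p = 0.0495) were the 2 of 38 that passed.

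**Figure D4:**
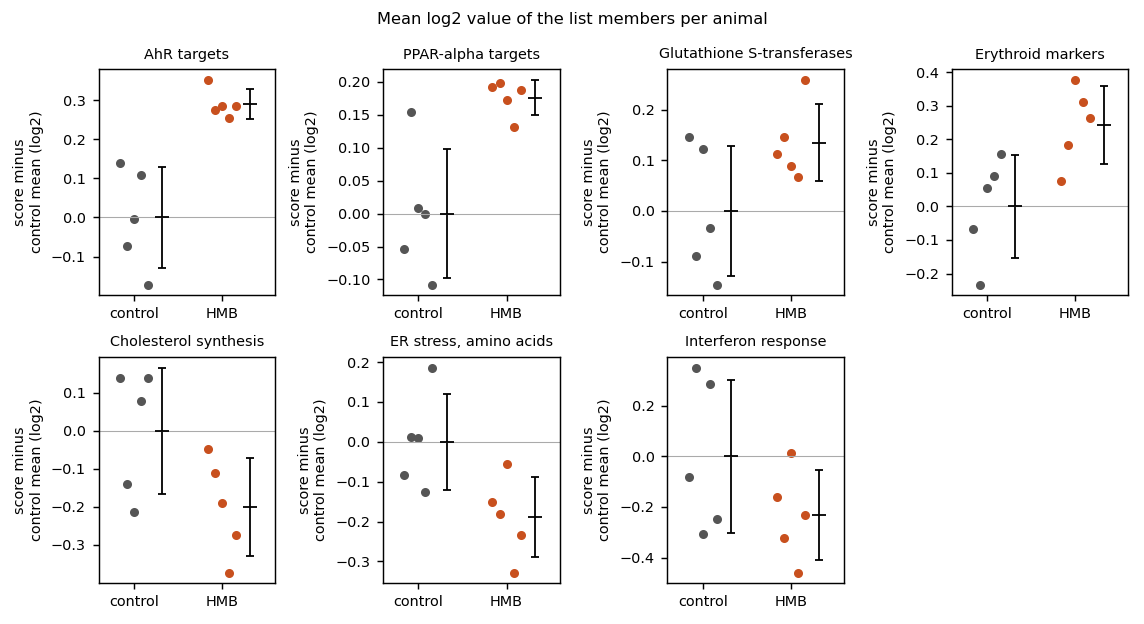
Mean log2 value of the measured members of 7 gene lists in each animal, minus the control mean (y axis), for 5 control and 5 HMB rats with group mean and SD. The AhR targets separate the groups without overlap. None of the 7 differences passed the exact permutation test after adjustment over 38 lists. In that test 1 list alone could not pass, even with complete separation of the groups.

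Among conjugation and drug metabolism genes, the glutathione S-transferases had 0 called of 19 measured members, and adjusted over the list alone 1 fell, Gstm3, with a log2 difference of -0.39 (adjusted p = 0.0639 over all genes). Their median was 0.10, with Mgst3 at 0.24 and Gsta1 at 0.23 (camera adjusted p = 0.0447, and adjusted p = 0.685 with an estimated correlation). The call was lost without control 2, control 4, control 5, HMB 1, HMB 2 or HMB 5 (adjusted p up to 0.122), with HMB 3 to 5 left out, and with the poly-A signal as a covariate, where the median was 0.06. Fry did not call the list either (adjusted p = 0.184), and in all the call was lost in 12 of 20 settings. Gsta3 differed by 1.23 ± 0.37 (SE, n = 5 per group, limma adjusted p = 0.0856). Targets of the receptors CAR and PXR numbered 21 measured, with 0 called and a median of 0.02, and adjusted over the list alone the same Gstm3 fell. Among them, Cyp3a23-3a1 was at 13.08 in controls and 13.10 in HMB (adjusted p = 0.888), and Abcc3, an efflux transporter, differed by 1.18 ± 0.37 (adjusted p = 0.0927). Cyp2b1 and Cyp2b2 had no probe set of their own. A probe set that the annotation assigns to 2 members of this list at once entered no gene or list test, and the list's median leaves it out. That probe set rose by 1.40 ± 0.27 (limma adjusted p = 0.0341 over probe sets, and 0.042 after cyclic loess), from 9.54 ± 0.62 (SD, n = 5) to 10.94 ± 0.42. It was singled out after its values were seen. NRF2 targets, genes of the antioxidant response, had 0 called of 21, also when adjusted over the list alone, with a median of -0.02 and a mean of 0.10. UDP-glucuronosyltransferases had 0 called of 9 under both adjustments and a median of 0.10. Of 15 sulfotransferase genes, Sult5a1 rose by 0.46 ± 0.08 (adjusted p = 0.0294), alone also when adjusted over the list alone, and the median was 0.06.

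Lists of sterol synthesis, the unfolded protein response and interferon lay lower in HMB by camera. All 3 calls were lost when the lowest 25% of mean levels was left out. In that setting 3 gene lists shifted by HMB were called, all 3 higher and 2 of them among the original 7. The AhR list was not tested there. Of 21 measured cholesterol synthesis genes 0 were called, 19 were below 0, and adjusted over the list alone 8 fell. Squalene epoxidase, Sqle, had a log2 difference of -0.56 ± 0.15 (SE, n = 5 per group, limma adjusted p = 0.0714), Idi1 one of -0.38, Stard4 of -0.36 and Srebf2, which encodes the controlling transcription factor, of -0.21. The median was -0.22 (camera adjusted p = 0.00766, and adjusted p = 0.685 with an estimated correlation). Cyclic loess left a median of -0.14 (camera adjusted p = 0.0224). Without control 1 the list's adjusted p was 0.0541, and the median shrank to -0.09 with the poly-A signal as a covariate and to -0.12 with HMB 3 to 5 left out, where the call was lost as well. Among 28 genes of endoplasmic reticulum stress and the amino acid response, Psph, the last enzyme of serine synthesis, fell by 0.49 ± 0.09 (adjusted p = 0.0307) and 27 did not pass. After cyclic loess Psph had an adjusted p of 0.0709. In all 4 fell when adjusted over the list alone, namely Psph, Atf5 at -0.37, Fgf21 at -0.87 and Ddit3 at -0.33, and 1 rose, Edem1, named here after its values were seen. That list had a median of -0.15 (camera adjusted p = 0.0116, and adjusted p = 0.685 with an estimated correlation), and with HMB 3 to 5 left out its median of -0.09 no longer passed. Of 31 interferon response genes 0 were called under either adjustment, over all genes or adjusted over the list alone, and 25 were below 0. Mx2 was at -0.89, Psmb8 at -0.50, Irf9 at -0.39 and Oas1b at -0.45, and the median was -0.29 (camera adjusted p = 0.0364, and adjusted p = 0.685 with an estimated correlation). That call was lost without control 1, control 2, control 4, HMB 2 or HMB 4 (adjusted p up to 0.172), and the interferon response median log2 was -0.15 without control 4 or HMB 4 and -0.17 without control 2.

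Camera called 7 of 38 lists, 4 higher and 3 lower in HMB. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, while fry called 2. After cyclic loess camera called 10 gene lists shifted by HMB, 4 higher and 6 lower, with the 7 joined by the cell cycle (adjusted p = 0.0132), acute phase (adjusted p = 0.0396) and hepatocyte marker (adjusted p = 0.0403) lists, all lower. By list means per animal 0 of 38 passed the exact permutation test after adjustment, with 6 at an unadjusted p under 0.05. The unadjusted exact permutation p was 0.00794 for AhR, 0.0159 for PPAR-alpha and for the circadian clock, and 0.0238 for erythroid markers. It was 0.0317 for ER stress and 0.0476 for the acute phase. The clock, ER stress and acute phase means were lower in HMB. The smallest p that 252 assignments allow, 0.00794, cannot pass that adjustment in 1 list alone. This result therefore does not argue against a shift of any list. Of 100 splits of the 10 animals into 5 and 5, the real one included, 55 gave at least 7 lists by camera, and the median of the other splits was 7. Leaving out control 2 left 4 lists, all among the 7. With HMB 3 to 5 left out, 4 lists passed, 3 of them among the 7.

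Single members fell in 5 further lists that camera did not call in the deposited values. In the cell cycle list of 37 genes, Ccnd1 fell and 36 did not pass. Adjusted over the list alone, 3 fell, adding Aurka at -0.72 and Rrm1 at -0.37, while the proliferation marker Mki67 was at 0.17 (adjusted p = 0.58). Rora fell alone of 18 circadian clock genes under both adjustments, and Bhlhe40 of that list was at -1.64 (adjusted p = 0.0927). Of 24 acute phase genes, Stat3, the transcription factor of that response, fell by 0.59 ± 0.12 (SE, n = 5 per group, limma adjusted p = 0.0384), also alone when adjusted over the list alone. Phlda3 fell by 0.66 ± 0.14 (adjusted p = 0.0461) alone of 18 p53 targets under both adjustments, and Cdkn1a was at -0.29 (adjusted p = 0.415). Of 26 genes of lipoproteins and lipid droplets, Apoa4, an apolipoprotein, fell by 0.67 ± 0.13 (adjusted p = 0.0371). Of these 2 fell when adjusted over the list alone, Apoa4 and Lpl at -0.67, and 1 rose, Mttp at 0.24. After cyclic loess Ccnd1 and Rora were still called, and Stat3 (adjusted p = 0.0739), Phlda3 (adjusted p = 0.109) and Apoa4 (adjusted p = 0.0676) were not. List medians were -0.01 for the cell cycle, -0.09 for the clock, -0.04 for the acute phase, -0.13 for p53 and -0.04 for lipoproteins. In the cyclic loess values, where camera called the cell cycle and acute phase lists, their medians were -0.11 and -0.07.

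In the remaining pathway lists no gene was called over all genes. The growth hormone, IGF and thyroid axis had a median of -0.12 over 23 genes, and adjusted over the list alone 2 fell, Dio1, the thyroid hormone deiodinase, at -0.42 (limma adjusted p = 0.0547 over all genes) and Onecut1, a hepatocyte transcription factor, at -1.99 (adjusted p = 0.0557 over all genes). Adjusted over the list alone, 0 genes passed for each of the other 9 lists. Fatty acid synthesis (23 genes) had a median of -0.17, bile acid synthesis and transport (21 genes) one of 0.08, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.39 (adjusted p = 0.273). Gluconeogenesis and glycolysis (22 genes) had a median of -0.08, amino acid catabolism and the urea cycle (30 genes) 0.03, heme synthesis (7 genes) -0.14 and the heat shock response (15 genes) -0.10. Immediate early genes (15 genes), a mark of tissue handling, had a median of 0.05, with a mean of 0.00 and a camera direction of down. Y-linked genes were represented by 2, too few for a test, with Eif2s3y at 0.26 (called when adjusted over the list alone) and Uty at 0.02. Male-biased liver genes (13 genes) had a median of 0.01, and female-biased ones (12 genes) had a median of 0.05, a mean of -0.05 and a camera direction of up.

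Markers of cell types other than hepatocytes were called in 0 cases over all genes. Erythroid markers had a median of 0.26, with all 7 measured members above 0 (camera adjusted p = 0.0259, and adjusted p = 0.685 with an estimated correlation). Slc4a1, the red cell anion exchanger, was at 3.09 ± 0.20 (SD, n = 5) in controls and 3.49 ± 0.15 in HMB, Epb42 differed by 0.26 and Alas2, the erythroid heme synthesis enzyme, by 0.40, and adjusted over the list alone Slc4a1 and Epb42 rose. The list's call was lost without control 1 or control 2 (adjusted p up to 0.0756) and with the lowest 25% of mean levels left out (adjusted p = 0.0775 for the erythroid markers median log2), and its median was 0.13 with the poly-A signal as a covariate and 0.16 with HMB 3 to 5 left out, both without a call. Adjusted over the list alone, 1 marker rose in each of 4 other lists, namely Defa5 of neutrophils (10 genes, median 0.04), Cuzd1 of pancreatic acini (14 genes, 0.14), Lep of adipocytes (8 genes, -0.03, with a mean of 0.06) and Cyp1a2 of pericentral hepatocytes (12 genes, 0.07). With 0 passing when adjusted over the list alone, the medians were -0.03 for hepatocyte markers (13 genes), -0.01 for periportal hepatocytes (12 genes, with a mean of 0.01) and -0.04 for Kupffer cells and macrophages (16 genes). They were 0.01 for T, NK and B cells (18 genes), -0.15 for endothelial cells (14 genes), -0.12 for stellate cells and fibroblasts (19 genes), -0.05 for cholangiocytes (10 genes) and 0.15 for mast cells (8 genes). Under cyclic loess the medians were 0.04 for pancreatic acini, 0.05 for mast cells, -0.08 for endothelial cells and -0.06 for stellate cells. Those of neutrophils, at -0.06, and Kupffer cells, at 0.06, changed sign, and that of hepatocyte markers was -0.08. The 31 lists that camera did not call in the deposited values had adjusted p from 0.0835 to 0.984.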

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

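The test of a narrower range of values, the 3 tests of a lower messenger RNA yield and the test of an exchange of HMB 1 with control 1 were chosen after the results had been seen; the others were written before.

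Rises lay among dim genes and falls among bright genes, with 96.9% of calls upward among the 3555 dimmest genes and 18.9% among the 3554 brightest. A lower yield of messenger RNA in HMB livers, which the poly-A signal would track, is argued against as the whole cause, because the difference in array SD of -0.0734 ± 0.0157 (SE) stayed at -0.0579 ± 0.0219 with that signal as a covariate. A technically narrower range of values on the HMB arrays may account for the pattern and cannot be told apart from a change in the livers. After cyclic loess the excess of upward calls among dim over bright genes went from 78.0 to -2.56 percentage points, but 3 calls were left among the dimmest genes and 13 among the brightest, and that correction removes a trend with level from any source, for which reason the test was taken as undecided after its value was seen. An effect of HMB feeding itself stays open and untested.

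The AhR and PPAR-alpha lists were higher in HMB. The shift of the arrays with expression level is argued against as the whole cause, since the AhR median of 0.27 lay at percentile 99.88 of 10000 random lists matched on level (their median 0.05) and the PPAR-alpha median of 0.18 at percentile 100 (their median -0.04), although the AhR targets median log2 was 0.16 after cyclic loess and after quantile normalization, which ended its call (adjusted p = 0.0742), while that of PPAR-alpha was 0.25 after cyclic loess. A lower messenger RNA yield is argued against as the whole cause as well, because with the poly-A signal as a covariate the differences between the groups in list means were 0.32 ± 0.09 (SE) for AhR and 0.17 ± 0.07 for PPAR-alpha, against 0.29 and 0.18 without it. HMB 1 and HMB 2, whose poly-A signal was like that of controls, lay above all 5 controls in both lists. For PPAR-alpha the margin was small, with both at 9.09 and control 2 at 9.05. These are 2 animals, and HMB 1 has a dose label of 0 ppm. Both lay below all controls in the 3' minus 5' signal of GAPDH, and a difference in RNA quality was not tested as a cause. A response to HMB could account for both shifts as a hypothesis, found and tested on the same animals. The correlation of genes within a list stays open, since both calls were lost when it was estimated (adjusted p = 0.577 and 0.685), as does any difference between cages.

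HMB 1 has a dose label of 0 ppm. On the 200 genes that best separated the other 9 animals, with the control mean at 0 and the mean of the other HMB animals at 1, it lay at 0.569, while the controls, each placed the same way, lay at 0.575, 0.0256, 0.270, 0.0569 and 0.127 and HMB 2 to 5 at 0.820, 0.508, 0.934 and 1.06. A control animal under an HMB title cannot be told apart from a treated one here, because control 1 lay as far over as HMB 1. An exchange of HMB 1 with control 1 cannot be told apart either, since HMB 1 lay 0.0908 above control 1 on genes chosen without both, where the 25 pairs of a control and an HMB animal ranged from 0.0856 to 0.946. HMB 1 had the highest AhR list mean of the 10 animals, 0.35 above the control mean, and Cyp1a1 at 4.89, above all 5 controls (3.91 or lower).

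For 3 of the 4 counts, at most 2 of 100 splits of the animals into 5 and 5, the real one included, gave a count as large. That argues against chance for these counts without excluding it. The 528 probe sets and the 179 probe sets changed at least 1.5-fold were each reached by 1 split, the real one, with at most 205 and 73 in the others. The 244 genes were reached by 2 splits, and the higher, with 336, was the split that exchanges HMB 1 with control 1. That same split gave 205 probe sets, 73 changed at least 1.5-fold and 1 gene list, each below the real split. The 7 gene lists were reached by 55 splits, with up to 13 lists in the others, so for that count the splits did not argue against chance.

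In 222 groups of 5 animals tested, 13 had 1 animal far from the other 4, with a gap to the nearest above 0.71 of the group's range; chance gives about 1 in 20, or 11.1. For genes in controls, this share of the range was 0.732 for Cyp7a1 (control 4), 0.820 for Cyp1b1 (control 3), 0.732 for Oas1b (control 2), 0.762 for Apoa4 (control 4), 0.754 for Onecut1 (control 3) and 0.722 for Uty (control 3). In the HMB group it was 0.880 for Prcp, with HMB 5 at 6.87 and the next animal at 5.82. For list means it was 0.7103 for sulfotransferases (control 1), 0.734 for bile acid genes (HMB 3), 0.898 for the acute phase in controls (control 1) and 0.766 in HMB (HMB 1), and 0.712 for cholangiocyte markers in controls (control 4) and 0.738 in HMB (HMB 4). In the control probe sets, which the comparison of genes does not use, the poly-A signal differed by 0.306 between HMB and control, with HMB 3, HMB 4 and HMB 5 above all controls.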

How the results depend on the processing

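The fits with quantile normalization, with the poly-A signal as a covariate, without HMB 3 to 5 and without HMB 1 and 2 were chosen after the data were seen. The 244 genes were chosen by their calls, so that their direction, kept in all 18 settings, could hardly have turned; their median size relative to the reported one ran from 0.82 to 1.07. Of 369 comparisons for the 20 genes with the largest changes, 146 kept direction and call, 220 kept the direction without the call and 3 turned, the second probe sets of Vxn at 0.16, Ajuba at 0.011 and Rora at 0.22. For all 69 genes compared, 316 of 1264 comparisons lost a call and 33 gained one, and a change of sign in a gene without a call, as in Mki67 and Uty, was not counted as a turn. Of the lists, PPAR-alpha kept its call in 19 of 20 settings and AhR in 17 of 19. The AhR list was not tested with the lowest mean levels left out, where lists under 5 measured members were dropped. Its count therefore does not cover that setting. Of 20 settings, ER stress kept its call in 16, cholesterol synthesis in 14, erythroid markers in 13, interferon in 11 and glutathione S-transferases in 8.

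Against the reported 528 probe sets changed by HMB, 179 probe sets changed by HMB at least 1.5-fold and 244 genes changed by HMB, the counts in that order were 125, 72 and 82 after cyclic loess, 106, 61 and 62 after quantile normalization, 2000, 312 and 976 with the first residual component as a covariate, and 2094, 730 and 704 without HMB 1 and 2. Array weights gave 925 probe sets and 411 genes, and the dose label for HMB 1 gave 30 genes. The 3 counts were 0 without HMB 3 to 5, with the poly-A signal as a covariate and at an adjusted p of 0.01, although 1612 and 1914 genes had an unadjusted p under 0.05 in the first 2 of these. limma treat against 1.2-fold called 0 probe sets, with 769 at an unadjusted p under 0.05. Leaving out 1 animal at a time gave 0 to 1653 probe sets, 0 to 378 at 1.5-fold, 0 to 1014 genes, 4 to 10 gene lists shifted by HMB and 0 list means. Against the 7 lists, 3 passed with the lowest 25% of genes left out, all higher and 2 of them among the 7. The AhR list was not tested there. Without HMB 3 to 5, 4 lists passed, with an estimated correlation 0 and by fry 2. The cause of these moves was not tested.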

Other observations

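The values in this part were chosen after they were seen. Abcc3, Gsta3, Akr7a3 and Aldh1a1, 4 genes of drug metabolism, varied more among controls than among HMB rats. The CAR and PXR list and the NRF2 list, which hold these genes, had medians of 0.02 and -0.02 with no member called. The CAR and PXR median leaves out the probe set assigned to 2 members of that list, which rose by 1.40. Abcc3, a conjugate transporter, lay between 5.89 and 6.46 in the 5 HMB rats on the log2 scale, at 5.89 and 5.93 in controls 1 and 3, and between 3.95 and 5.00 in the other 3 controls. Gsta3, a glutathione S-transferase, lay between 8.58 and 9.23 in HMB, at 8.74 and 8.61 in controls 1 and 3, and between 6.81 and 7.08 in the others. Akr7a3 and Aldh1a1, reductases and dehydrogenases of aldehydes, were at 11.81 and 11.57 in control 1, at 11.53 and 11.86 in control 3, and had HMB means of 11.53 and 11.76. None of these 4 genes was called (limma adjusted p from 0.0856 to 0.212).

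The probe set with the largest rise among those without a gene name had the values 3.73, 3.17, 8.78, 2.55 and 5.94 in controls 1 to 5 and lay between 8.91 and 9.72 in HMB. It rose by 4.46 ± 0.91 on the log2 scale (SE, n = 5 per group, limma adjusted p = 0.0386, and adjusted p = 0.052 after cyclic loess). Onecut1 spread from 6.24 to 9.32 among HMB rats, with a control range of 9.15 to 10.37, and Bhlhe40 from 3.92 to 6.83 against 6.29 to 7.99. Cyp2c12, a female-biased cytochrome P450, was at 10.11 ± 0.82 in controls and 8.97 ± 0.56 in HMB (adjusted p = 0.0983). The Y-linked genes Eif2s3y and Uty lay between 8.63 and 9.17 and between 7.56 and 8.02 in all 10 animals, above the array medians of 4.33 to 4.41. These values gave no sign of a difference in sex between the groups.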
